A study of Mus musculus with 12 samples.

How the data were processed

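RNA was measured by sequencing in endothelial cells sorted from the bone marrow of untreated B6 mice, obtained by crushing the bones. Per the labels, biological triplicates of 4 sorted populations came from 6 mice, cDNA was made with a low-input kit from sorted cells lysed in TRIzol, and the libraries were read at 150 bp. The 12 libraries were grouped by the population in their titles, with 3 libraries in each of CD200-high, type H, arterial and sinusoidal. The last group is called the libraries labelled sinusoidal, since Ly6a, the transcript of its antigen Sca1, lay far below the other populations.

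The authors deposited 1 table of 17362 genes, named by mouse symbols, with 1 column per library. The values deposited are in log2 units: log2 CPM (counts per 1e6 reads) of an effective library size, with 0.5 read added to each count. Undoing the log and multiplying by the effective size gave whole reads within 0.01 for 100% of the values in every library, and reads and depths below were recovered in this way. The effective size differed from the listed reads by a factor that varied between libraries, so the authors had applied a scaling, whose method is not stated. The authors' notes name Trimmomatic, STAR, SAMtools, deepTools, featureCounts and R 4.3, without settings. They give a human genome build although the samples and symbols are mouse, so no coordinates are reported. The strand counted is not stated, so genes that overlap on opposite strands are uncertain, and so are near-identical gene copies such as the haemoglobin and osteocalcin genes.

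Listed reads ranged from 7.33 to 21.6 M (M, 1e6 reads) per library. The chi-square per degree of freedom between replicates ran from 54.5 to 128, where counting error alone would give about 1. This ratio rests mostly on abundant genes, and depth still limits genes with few reads. Floors and the fold bounds built on them use 3 reads per library and cover counting error only, since reads were not tied to molecules.

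Each of the 6 comparisons between populations was tested with limma 3.58.1 in R 4.3.3. The test used a mean-variance trend and group means on the deposited log2 values, with all 12 libraries in 1 fit and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The filter kept genes with at least 10 reads, scaled to the mean effective size of 15.9 M (0.63 CPM), in at least 3 libraries. It kept 17086 genes and removed 276. The plan had assumed normalised counts and a pseudocount of 1; as the table already holds log2 values, these were tested as they stand, and the pseudocount of 1 was run as an alternative. Fold changes are on the scale with 0.5 read added and understate the change of low genes. A gene was called highest in a population when it passed against each of the other 3.

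The comparisons, the test, the filter, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except those said to be added. The 28 lists held 481 genes, 465 of them in the table, 17 lists of endothelial types and pathways and 11 of other cells a marrow sort could hold. Pan-endothelial, arterial, sinusoidal, capillary, tip cell and basement membrane, and venous and inflamed lists described vessels. Notch signalling, niche factors, immune checkpoint and tolerance, nitric oxide, primary cilium, autophagy, MHC class I, MHC class II, interferon response, cell cycle, and immediate early and heat shock lists described programmes. Lymphatic endothelium, erythroid, neutrophil, macrophage, B and plasma cell, T and NK cell, megakaryocyte and platelet, stem and progenitor, stromal and bone, mural and skeletal muscle lists described other cells. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of the lists called by camera in the 6 comparisons, 13, 6, 19, 18, 16 and 18 of 28 in the order of the report, 0, 2, 8, 7, 6 and 6 kept the call with an estimated correlation.

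The rule for named genes took the 5 sorting antigens in every comparison, with Ift20, Nos3 and Cd200 in the 3 of CD200-high. It added the 8 largest rises and 8 largest falls in each comparison of CD200-high and the 5 and 5 in each of the others, and the 8 genes highest in each population. These had to pass the test, have 3 values in 1 population above the 3 in the other, and average at least 100 normalised reads in the higher one, and gene models without a name were left out. It also added up to 4 genes with the smallest adjusted p from each list. Of all genes tested, 30.9% to 46.8% had such separated values, where chance gives 10% for 3 libraries against 3.

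The labels give the same mouse numbers in all 4 populations, so libraries of the same number were treated as paired in an alternative with the replicate number as a block. Deviations from the population means correlated between same-numbered libraries at -0.05 to 0.08 over 12183 genes, with a median of 0.03 and 0 of 18 pairs over 0.1. Between different numbers they ran from -0.09 to 0.05, and 9 of 12 libraries were closest to their own number. The labels speak of 6 mice and give only 3 numbers, so whether a number stands for 1 mouse is open.

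The alternatives tried were pseudocounts of 0.1 and 10, no filter, a filter at 50 reads, quantile normalization, rescaling to the same total, the replicate block, fits of only the libraries compared, limma without the trend, a log2 difference of at least 1, the other list tests and leaving out each library. Added after the data were seen were a pseudocount of 1, limma voom weights on the recovered reads, fits without the libraries labelled sinusoidal, and each library shifted to the same median of the pan-endothelial list. The test was tried on simulated data with 16852 genes, in which limma called 0 of 50 genes changed by 1.5-fold, 6 of 49 by 2-fold, 22 of 50 by 4-fold and 24 of 50 by 8-fold, none in the wrong direction, and 4 of 16623 unchanged genes. At each of these fold changes more than 0.5 of the changed genes were missed in the simulation. Nearly all simulated genes were unchanged, while 10.2% to 28.7% were called in the data, so the adjusted threshold was stricter in the simulation. The simulated spread was also set relative to the mean over all 4 populations. The shares missed therefore do not give those of the real comparisons.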

Results

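RNA was sequenced from endothelial cells sorted out of crushed mouse tibia, femur and iliac bone. The 12 libraries fall into 4 sorted populations with 3 libraries each. CD200-high capillaries were selected as CD200Hi, Sca1+, CD31+, EMCN- and CD45-, and type H vessels, a bone vessel type rich in endomucin, as EMCN+, Sca1+, CD31+ and CD45-. Other arterial cells were selected as CD200-, Sca1+, CD31+ and CD45-, and the libraries labelled sinusoidal as CD31+, Sca1+ and CD45-. As labelled, this last gate contains the gates of the other 3 populations. The type H label names no CD200 gate and the arterial label no EMCN gate, so those 2 gates can overlap. The reads listed over all genes came to 12.7, 15.8 and 7.33 M in the CD200-high libraries of replicates 1, 2 and 3, and to 20.2, 17.5 and 16.2 M in type H. They came to 16.2, 15.4 and 9.55 M in the arterial libraries and to 16.6, 21.6 and 18.4 M (M, 1e6 reads) in those labelled sinusoidal. Values are log2 CPM (counts per 1e6 reads) as mean ± SD of 3 libraries, differences are log2 ± SE, and adjusted p values are from limma. In each named gene that passed the test, the 3 libraries of the higher population all lay above the 3 of the lower, which chance gives in 10% of genes. Of all genes tested, 30.9% to 46.8% had this separation. It was a condition of naming the largest rises and falls and the genes highest in a population, so it does not add support for them.

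Of the sorting antigens, Ly6a, Emcn and Cd200 had transcript levels in the libraries labelled sinusoidal well below the other 3 populations, Pecam1 lay lower by a smaller margin, and Ptprc lay between arterial and CD200-high. Ly6a, which encodes Sca1, reached 10.19 ± 0.35 log2 CPM in CD200-high, 8.92 ± 0.39 in type H and 9.78 ± 0.13 in arterial libraries (n = 3 each), against 4.05 ± 0.71 in the libraries labelled sinusoidal, whose label gives Sca1+. Emcn, the endomucin gene, stood at 8.26 ± 0.42 in CD200-high, 9.02 ± 0.03 in type H, 6.56 ± 0.45 in arterial and 2.08 ± 0.81 in the libraries labelled sinusoidal. Cd200 was highest in CD200-high at 9.81 ± 0.02, against 7.80 ± 0.32 in type H, 7.68 ± 0.11 in arterial and 5.43 ± 0.08 in the libraries labelled sinusoidal. Pecam1, which encodes CD31, stood at 8.37 ± 0.55, 8.97 ± 0.10, 7.24 ± 0.19 and 6.22 ± 0.21 in the same order of populations. Ptprc, which encodes CD45 and against which all 4 populations were gated, stood at 5.38 ± 0.65, 3.98 ± 0.57, 7.42 ± 0.23 and 6.54 ± 0.31 in that order.

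**Figure D1:**
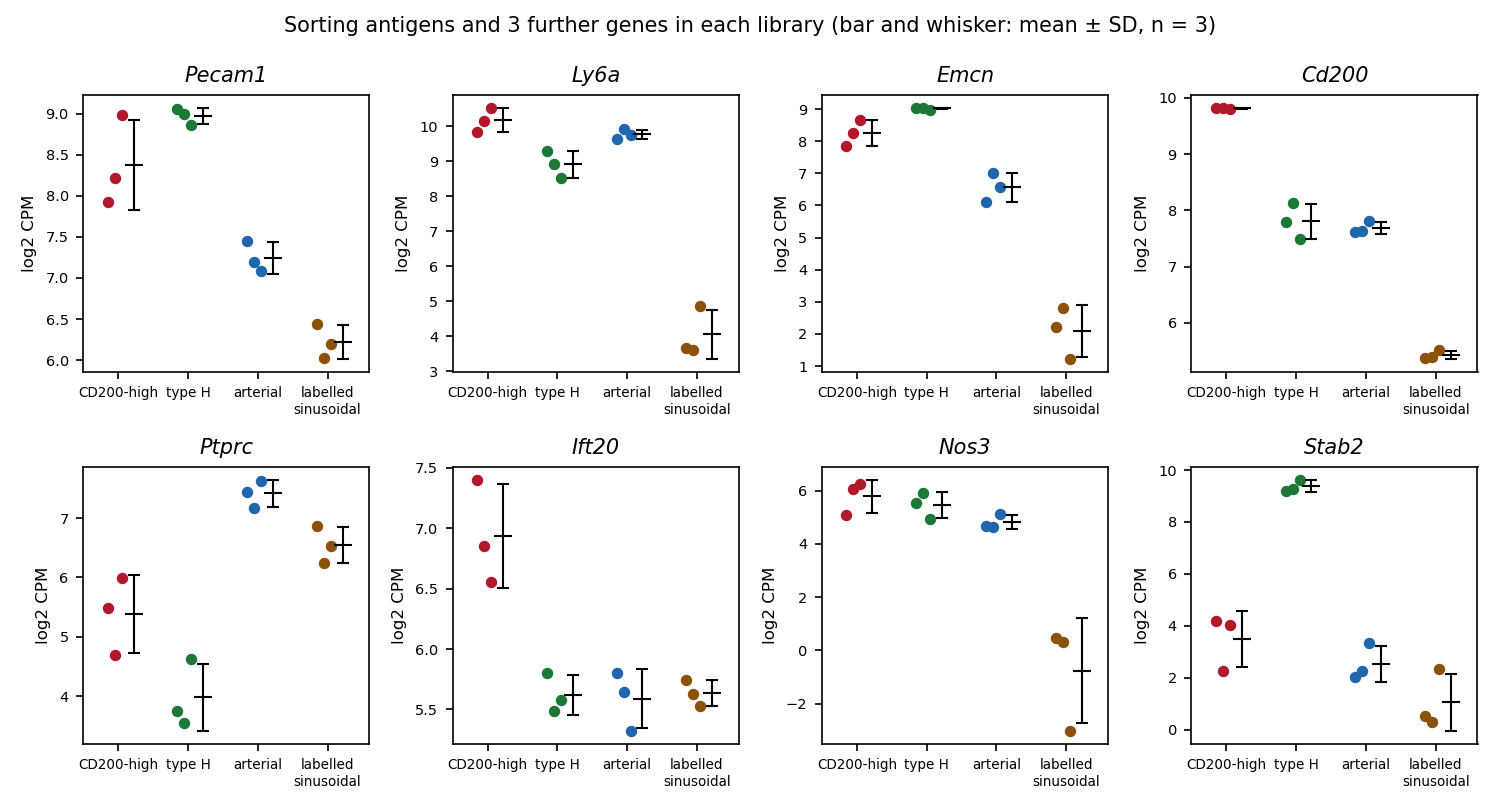
Levels of 8 transcripts in each of the 12 libraries: points are libraries, bars are the mean and SD of 3 libraries, and the vertical axis is log2 CPM. Ly6a and Emcn lay lowest in the libraries labelled sinusoidal, at means of 4.05 and 2.08, and Cd200 and Ift20 lay highest in CD200-high, at means of 9.81 and 6.94.

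The comparison of CD200-high with arterial libraries asks how capillary cells selected for CD200 differ from cells gated as CD200- and labelled arterial. Cd200 was higher in CD200-high by 2.13 ± 0.16 log2 (adjusted p = 4.74e-05), and Aplnr, the apelin receptor gene, rose from 7.83 ± 0.29 in arterial to 10.25 ± 0.14 log2 CPM (difference 2.42 ± 0.23, adjusted p = 0.000175). Nrp2, a co-receptor for vascular growth factors, was higher by 3.45 ± 0.42 (adjusted p = 0.000521), and Tie1, an endothelial receptor gene, by 2.10 ± 0.30 (adjusted p = 0.00116). Arterial libraries held far more RNA of the adipokine gene Adipoq, at 8.87 ± 0.51 against -2.03 ± 0.55 (difference -10.89 ± 0.51, adjusted p = 2.01e-06). Vcam1, a leukocyte adhesion molecule, fell by 3.17 ± 0.30 in CD200-high (adjusted p = 0.000191). Cxcl12, the chemokine that holds blood stem cells in the marrow, fell from 12.54 ± 0.66 to 10.12 ± 0.30 (difference -2.43 ± 0.45, adjusted p = 0.00501). Cxcl12 is grouped below with Lepr and Adipoq as a gene of reticular stroma and adipocytes, and all 3 were lower in CD200-high. Which cells carry the difference in Cxcl12 was not tested. BC055402 was at least 192-fold higher in CD200-high than the floor of 3 reads per library in arterial, where it had no reads. Limma called 2204 of 17086 genes, 811 higher and 1393 lower in CD200-high.

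Endothelial genes shared by vessel types leaned towards CD200-high. Of 16 pan-endothelial genes, 5 rose and 0 fell (10 rose when adjusted over the list alone), and camera gave adjusted p = 6.83e-06, or adjusted p = 0.108 with an estimated correlation. Of 17 capillary genes, 7 rose and 0 fell (9 rose adjusted over the list alone; camera adjusted p = 1.53e-05, adjusted p = 0.108 with an estimated correlation). Of 18 immediate early and heat shock genes, which handling of cells also induces, 7 rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 2.2e-06, adjusted p = 0.108 with an estimated correlation). Of 17 arterial genes, 3 fell, with the matrix genes Mgp at -2.07 ± 0.36 (adjusted p = 0.0032) and Fbln5 at -1.97 ± 0.42 (adjusted p = 0.00999) among them. The arterial list as a group did not pass (median difference 0.17, camera adjusted p = 0.949, 3 genes adjusted over the list alone). None of the 14 Notch signalling genes passed, also when adjusted over the list alone (0 genes), with camera adjusted p = 0.289. Nos3, the endothelial nitric oxide synthase gene, was at 5.80 ± 0.62 and 4.82 ± 0.27, a difference of 0.98 ± 0.80 that did not pass (adjusted p = 0.475). Of 22 genes of nitric oxide synthesis and response, 2 fell and 0 rose (2 adjusted over the list alone, camera adjusted p = 0.149), among them Pts, an enzyme of the synthase's cofactor, at -1.75 ± 0.35 (adjusted p = 0.00711).

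Genes of proliferation and of blood cells were lower in CD200-high than in arterial libraries. Of 25 cell cycle genes, 18 fell (24 adjusted over the list alone), with the replication genes Mcm3 at -2.57 ± 0.28 (adjusted p = 0.000348) and Mcm6 at -2.21 ± 0.30 (adjusted p = 0.00102) and the mitotic cyclin Ccnb2 at -2.96 ± 0.48 (adjusted p = 0.00252). Camera gave the list adjusted p = 4.06e-13, or adjusted p = 0.0831 with an estimated correlation. Of 14 neutrophil genes, 13 fell (14 adjusted over the list alone; camera adjusted p = 1.71e-10, adjusted p = 0.114 with an estimated correlation), and these genes took 3.64 ± 0.776% of the reads in arterial and 1.02 ± 0.322% in CD200-high libraries. Of 12 B and plasma cell genes, 8 fell, and Ighm, the heavy chain gene of IgM, was at -2.46 ± 0.23 (adjusted p = 0.000155). The B and plasma cell list gave adjusted p = 2.27e-08 (10 genes adjusted over the list alone), or adjusted p = 0.0551 with an estimated correlation. Of 12 erythroid genes, 9 fell (10 adjusted over the list alone; camera adjusted p = 1.74e-07, adjusted p = 0.108 with an estimated correlation). Of 11 megakaryocyte and platelet genes, 9 fell (9 adjusted over the list alone; camera adjusted p = 7.63e-07, adjusted p = 0.0551 with an estimated correlation). Of 10 macrophage genes, 4 fell (6 adjusted over the list alone; camera adjusted p = 0.00163, adjusted p = 0.123 with an estimated correlation), with the complement gene C1qb at -4.20 ± 0.63 (adjusted p = 0.00152). Of 7 T and NK cell genes, 3 fell (5 adjusted over the list alone; camera adjusted p = 0.00153, adjusted p = 0.0845 with an estimated correlation). Of 8 MHC class II genes, 4 fell (7 adjusted over the list alone; camera adjusted p = 0.000415, adjusted p = 0.108 with an estimated correlation), with the invariant chain gene Cd74 at -2.56 ± 0.28 (adjusted p = 0.000348).

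Col1a2 and Sparc were higher and Lepr lower in CD200-high than in arterial libraries. Col1a2, a chain of bone collagen, stood at 14.67 ± 0.32 against 11.20 ± 0.21 log2 CPM (difference 3.47 ± 0.41, adjusted p = 0.000501), and Sparc, a bone matrix protein gene, at 15.01 ± 0.36 against 11.78 ± 0.14 (difference 3.23 ± 0.33, adjusted p = 0.000243). Bglap2, which encodes an osteocalcin and is nearly identical to Bglap so that reads may have been assigned to either, was higher by 4.50 ± 0.64 (adjusted p = 0.00118). Lepr, the leptin receptor gene of reticular stroma, fell by 4.76 ± 0.56 (adjusted p = 0.000459). Of the 16 stromal and bone genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone). The list took 10.9 ± 1.55% of the reads in CD200-high and 1.38 ± 0.150% in arterial libraries. Its camera adjusted p of 0.055 did not pass, and ranged from 1.15e-05 with voom to 0.556 with quantile normalization. It passed in 11 alternatives: pseudocounts of 10 and 1, rescaling to the same total, fits of only these 2 populations, voom, a shift of each library to the same pan-endothelial median, and 5 of the fits without 1 library. It was 0.0399 without CD200-high replicate 3, 0.00288, 0.0277 and 0.0176 without type H replicates 1, 2 and 3, and 0.046 without sinusoidal replicate 2. Kcnj8, a potassium channel gene of pericytes, was the 1 of 11 mural genes to pass, at 3.62 ± 0.58 (adjusted p = 0.00225; 1 gene adjusted over the list alone, camera adjusted p = 0.614). Ift20, which carries proteins to the primary cilium, was higher in CD200-high by 1.35 ± 0.25 (adjusted p = 0.00459). Among the 49 primary cilium genes 1 rose and 2 fell (1 and 1 adjusted over the list alone), with Tctn1 of the ciliary transition zone at -1.72 ± 0.31 (adjusted p = 0.00408). The median of that list was -0.09 and its mean -0.26, while camera pointed up without passing (adjusted p = 0.401). The autophagy, interferon response and mural lists also had medians and camera directions of opposite sign, and did not pass. With each library shifted to the same median of the pan-endothelial genes, an alternative added after the data were seen, 3670 genes were called, 137 higher and 3533 lower, and Ift20 no longer passed (difference 0.38, adjusted p = 0.528, against 0.00311 at the lowest over the alternatives). Without arterial replicate 1 the count was 1324 (538 higher and 786 lower), without arterial replicate 3 it was 1379 (551 and 828), and without arterial replicate 2 571 genes were higher and 922 lower. Limma without the trend gave 533 higher genes.

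The comparison of CD200-high with type H libraries sets capillaries gated as EMCN- against vessels gated as EMCN+. Emcn itself was at 8.26 ± 0.42 and 9.02 ± 0.03, a difference of -0.76 ± 0.37 that did not pass (adjusted p = 0.221), though it did with voom weights (adjusted p = 0.00831, against 0.779 at the highest over the alternatives). Type H libraries held much more RNA of genes typical of marrow sinusoids and venules. Tfpi, an inhibitor of coagulation, stood at 12.01 ± 0.27 in type H and 6.65 ± 0.53 in CD200-high (difference -5.36 ± 0.42, adjusted p = 1.15e-05), and Ackr1, a chemokine-binding receptor of venules, at 11.20 ± 0.09 and 5.83 ± 0.64 (difference -5.37 ± 0.61, adjusted p = 0.000151). Lrg1, a secreted vascular glycoprotein, fell by 3.98 ± 0.29 in CD200-high (adjusted p = 6.42e-06), and the adhesion gene Vcam1 fell by 4.20 ± 0.30 (adjusted p = 6.47e-06). CD200-high libraries in turn held Aqp7, a water and glycerol channel gene of capillaries, at 7.91 ± 0.72 against 2.97 ± 1.88 (difference 4.95 ± 0.77, adjusted p = 0.00131), and Car4, a carbonic anhydrase of capillaries, was higher by 9.65 ± 1.72 (adjusted p = 0.00313). Of the 17 capillary genes, 6 rose and 3 fell (7 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.535), but did with the pan-endothelial medians made equal (adjusted p = 0.0137). Limma called 2223 genes, 1138 higher and 1085 lower in CD200-high, and 1337 (681 and 656) when the 6 libraries of these populations were fitted alone. Without type H replicate 1 or 3, each left out alone, it called 1019 and 989 higher and 662 and 644 lower.

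All 14 genes of the sinusoidal list fell in CD200-high against type H (14 adjusted over the list alone), with camera adjusted p = 7.3e-19, or adjusted p = 0.00495 with an estimated correlation. Of 13 genes of venous and inflamed endothelium, 7 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00592, adjusted p = 0.0974 with an estimated correlation), with the adhesion gene Icam1 at -2.53 ± 0.31 (adjusted p = 0.000247). Of 17 arterial genes, 3 rose and 0 fell (4 adjusted over the list alone; camera adjusted p = 0.00345, adjusted p = 0.263 with an estimated correlation). Of 16 pan-endothelial genes, 5 fell (9 adjusted over the list alone; camera adjusted p = 5.38e-06, adjusted p = 0.227 with an estimated correlation), with the TGF-beta co-receptor Eng at -1.74 ± 0.19 (adjusted p = 0.000124) and Robo4, a guidance receptor of endothelium, at -1.93 ± 0.34 (adjusted p = 0.00304). Among 17 tip cell and basement membrane genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.925), and the member that fell, the nidogen gene Nid1, was at -2.35 ± 0.29 (adjusted p = 0.000275). Cav1, the main protein of caveolae, was higher by 3.03 ± 0.29 (adjusted p = 4.9e-05), and Nos3 differed by 0.34 ± 0.80 (adjusted p = 0.827). Of the 22 nitric oxide genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.635). Lgals1, a galectin that restrains T cells, was higher by 2.77 ± 0.15 (adjusted p = 1.12e-06) and Cd59a, a complement inhibitor, by 1.64 ± 0.23 (adjusted p = 0.000701), while Nectin2, a ligand of T and NK cell receptors, fell by 3.47 ± 0.49 (adjusted p = 0.000706). The 17 genes of immune checkpoint and tolerance had 3 that rose and 2 that fell (5 and 6 adjusted over the list alone). The list did not pass (camera adjusted p = 0.925).

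Bone matrix genes were higher in CD200-high than in type H. Col1a1, the other chain of bone collagen, was at 13.97 ± 0.37 against 2.76 ± 1.59 log2 CPM (difference 11.20 ± 0.61, adjusted p = 1.12e-06), and Spp1, which encodes osteopontin, at 12.64 ± 0.68 against 7.23 ± 0.95 (difference 5.41 ± 0.41, adjusted p = 8.89e-06). Cpz, a carboxypeptidase gene, had no reads in type H and was at least 2884-fold higher in CD200-high than the floor of 3 reads per library. Of the 16 stromal and bone genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 4.37e-11, adjusted p = 0.0473 with an estimated correlation), and their share of the reads in type H was 0.0843 ± 0.0434%. Adipoq was among the 2 that fell, at -8.66 ± 0.51 (adjusted p = 1.77e-06). The mural channel genes Kcnj8 and Abcc9 were both lower in CD200-high, each at -4.15 (SE 0.58 and 0.48, adjusted p = 0.000652 and 0.000157). Of the 11 mural genes, 2 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.635). Ift20 was higher by 1.32 ± 0.25 (adjusted p = 0.0041) and Kif3a, a motor of ciliary transport, fell by 4.70 ± 0.86 (adjusted p = 0.00355), and none of the other 47 primary cilium genes passed (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.635). The tip cell and basement membrane, Notch, immune checkpoint, immediate early, T and NK cell, and stem and progenitor lists had a median, mean or camera direction of opposite sign, and did not pass. With the pan-endothelial medians of the libraries made equal, 2252 genes were higher and 341 lower.

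The comparison of CD200-high with the libraries labelled sinusoidal asks how the capillaries differ from the cells of that label. General endothelial transcripts were much higher in CD200-high. Cdh5, which encodes VE-cadherin, was at 7.76 ± 0.65 in CD200-high and -0.47 ± 0.95 log2 CPM in the libraries labelled sinusoidal (difference 8.22 ± 0.44, adjusted p = 2.53e-07). Gpihbp1, which carries lipoprotein lipase into capillaries, was at 9.79 ± 0.44 and 1.92 ± 0.72 (difference 7.87 ± 0.31, adjusted p = 2.88e-08). Nos3 was higher by 6.56 ± 0.80 (adjusted p = 0.000109), Dll4, a Notch ligand of arteries, by 9.43 ± 1.06 (adjusted p = 5.88e-05), and Cd200 by 4.39 ± 0.16 (adjusted p = 1.4e-08). The libraries labelled sinusoidal held more RNA of B cell precursors and platelets. The B lineage gene Vpreb3 was at 10.88 ± 0.13 against 5.42 ± 0.31 (difference -5.47 ± 0.51, adjusted p = 1.52e-05). The platelet chemokine Pf4 was at 10.22 ± 0.08 against 4.01 ± 0.86 (difference -6.21 ± 0.47, adjusted p = 3.23e-06). Rag1, the recombinase gene of lymphocyte precursors, had no reads in CD200-high and was at least 541-fold higher in the libraries labelled sinusoidal than the floor of 3 reads per library. Limma called 4902 genes, 2407 higher and 2495 lower in CD200-high. Without sinusoidal replicates 1, 2 and 3 the lower genes numbered 1572, 1565 and 1590 and the higher ones 1967, 1867 and 1987, so that the majority turned.

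The sinusoidal, pan-endothelial, capillary and arterial lists were higher in CD200-high than in the libraries labelled sinusoidal. Of 14 sinusoidal genes, 9 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 2.86e-06, adjusted p = 0.0309 with an estimated correlation), with the scavenger receptor Stab1 at 5.02 ± 0.52 (adjusted p = 3.14e-05) and the VEGF receptor Flt4 at 4.39 ± 0.51 (adjusted p = 7.39e-05). Of 16 pan-endothelial genes, 13 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 3.12e-12, adjusted p = 0.0247 with an estimated correlation). Of 17 capillary genes, 15 rose and 0 fell (15 adjusted over the list alone; camera adjusted p = 4.19e-15, adjusted p = 0.0247 with an estimated correlation). Of 17 arterial genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.26e-08, adjusted p = 0.0247 with an estimated correlation). Of 17 tip cell and basement membrane genes, 13 rose and 0 fell (15 and 1 adjusted over the list alone; camera adjusted p = 2.15e-10, adjusted p = 0.0217 with an estimated correlation). Of 13 genes of venous and inflamed endothelium, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0363, adjusted p = 0.106 with an estimated correlation). The venous call was also lost with the stricter filter (adjusted p = 0.0632) and without CD200-high replicate 3 (adjusted p = 0.0653). Of 14 Notch signalling genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00125, adjusted p = 0.135 with an estimated correlation). Of 22 nitric oxide genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0192, adjusted p = 0.136 with an estimated correlation), led by Cav1 at 5.74 ± 0.29 (adjusted p = 2.04e-07). Of 17 genes of immune checkpoint and tolerance, 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00923, adjusted p = 0.0513 with an estimated correlation), with Cd59a at 2.93 ± 0.23 (adjusted p = 4.91e-06) and the galectin Lgals9 at -2.32 ± 0.27 (adjusted p = 6.72e-05). Of 32 interferon response genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 0.000455, adjusted p = 0.161 with an estimated correlation), with the antiviral gene Rsad2 at 3.99 ± 0.53 (adjusted p = 0.000195). Of 18 immediate early and heat shock genes, 10 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 9.01e-06, adjusted p = 0.0882 with an estimated correlation).

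Lists of B cells, megakaryocytes and progenitors were lower in CD200-high in the same comparison, while the neutrophil and macrophage lists did not pass. Of 14 neutrophil genes, 0 passed (0 adjusted over the list alone, camera adjusted p = 0.718), and of 10 macrophage genes 1 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.727). Of 12 B and plasma cell genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 1.36e-08, adjusted p = 0.0247 with an estimated correlation), and their share of the reads was 1.35 ± 0.0879% in the libraries labelled sinusoidal and 0.0305 ± 0.00809% in CD200-high. Of 11 megakaryocyte and platelet genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 5.28e-07, adjusted p = 0.0247 with an estimated correlation). Of 7 stem and progenitor genes, 5 fell (6 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.0309 with an estimated correlation), with Myb, a regulator of blood progenitors, at -6.94 ± 1.06 (adjusted p = 0.000528). Of 25 cell cycle genes, 24 fell (24 adjusted over the list alone; camera adjusted p = 7.79e-12, adjusted p = 0.0513 with an estimated correlation). Of 16 stromal and bone genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000455, adjusted p = 0.114 with an estimated correlation). Ift20 was higher in CD200-high by 1.30 ± 0.25 (adjusted p = 0.00213) and Ift43, also of ciliary transport, by 3.77 ± 0.46 (adjusted p = 0.000106), while Ift22 and Tctn1 fell by 2.48 ± 0.46 and 1.70 ± 0.31 (adjusted p = 0.00198 and 0.00167). Of 49 primary cilium genes 4 rose and 5 fell (3 and 4 adjusted over the list alone), and the list, with a median of 0.37, a mean of -0.08 and a camera direction of up, did not pass (adjusted p = 0.53). With every library rescaled to the same total, 1997 genes were higher and 3629 lower in CD200-high.

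**Figure D2:**
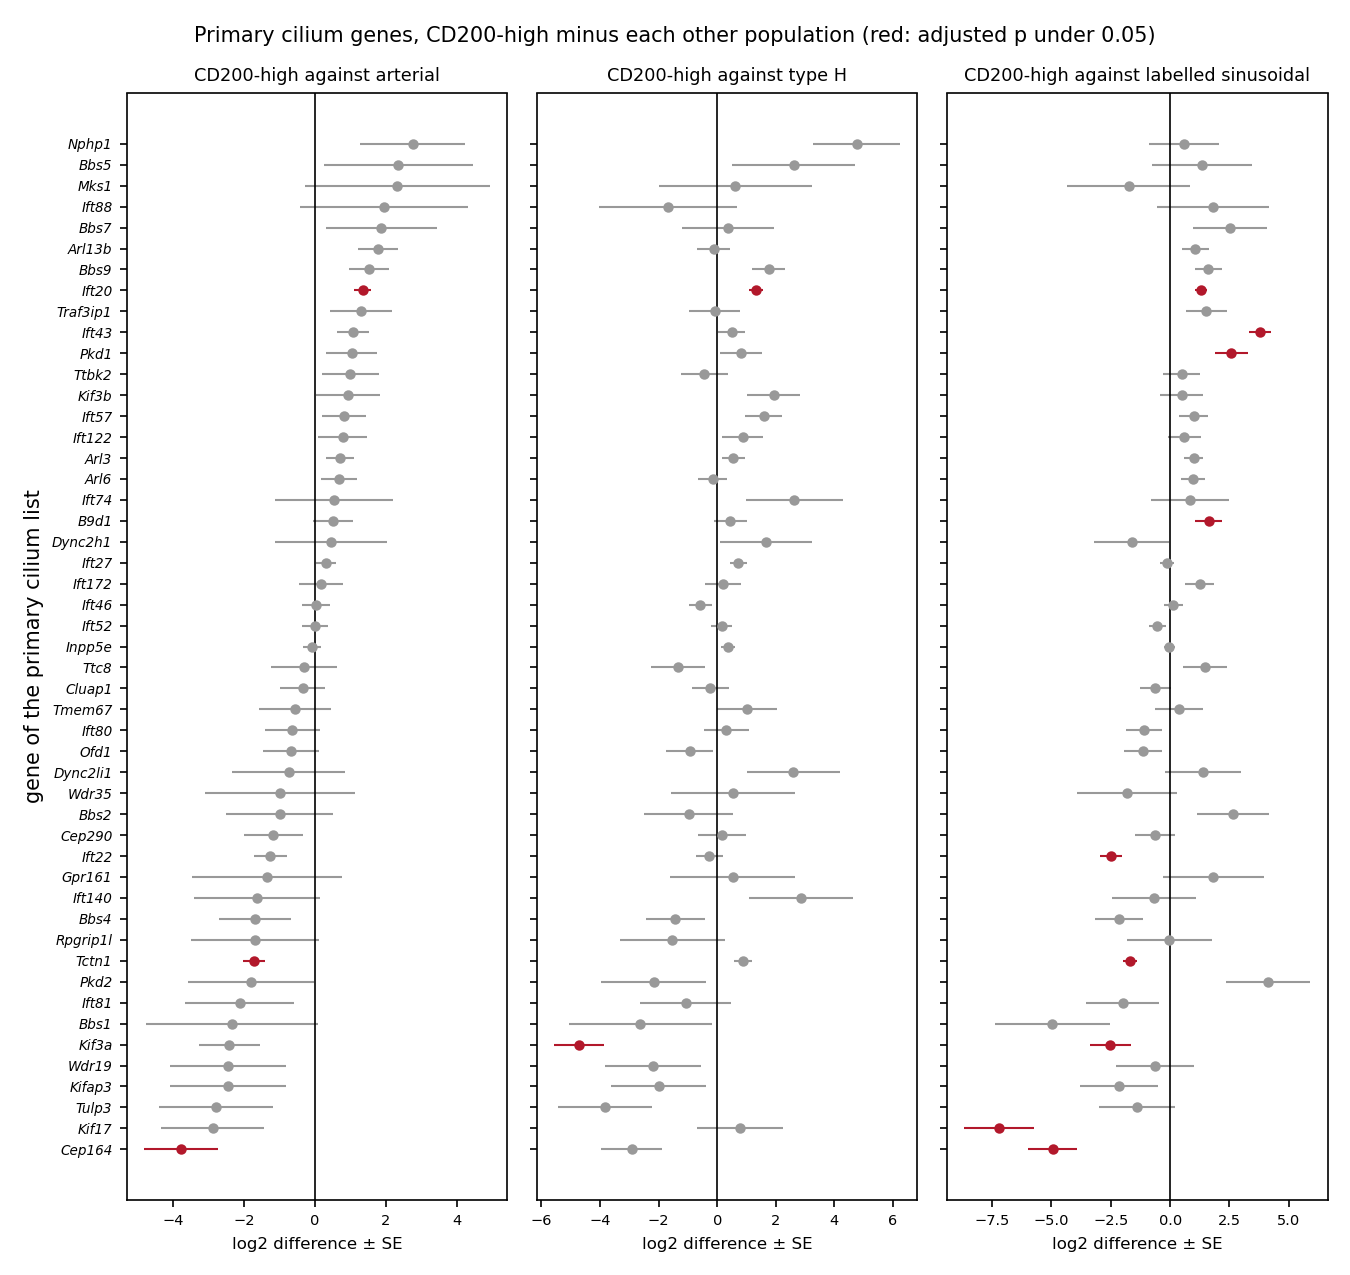
Log2 difference and SE of the 49 primary cilium genes between CD200-high and each other population, with genes at adjusted p under 0.05 in red. Ift20 was higher in all 3 comparisons, by 1.35, 1.32 and 1.30, but not past the test against arterial once the pan-endothelial medians were made equal (0.38), and Tctn1 was at -1.72 against arterial and -1.70 against the libraries labelled sinusoidal.

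The comparison of type H with the libraries labelled sinusoidal sets vessels gated as EMCN+ against cells of the sinusoidal label. Emcn was higher in type H by 6.94 ± 0.37 (adjusted p = 1.88e-07) and Ly6a by 4.87 ± 0.32 (adjusted p = 7.97e-07). Genes of the sinusoidal list were higher in type H, with Il6st, the shared receptor chain of the interleukin 6 family, at 11.76 ± 0.25 against 5.37 ± 0.54 log2 CPM (difference 6.39 ± 0.30, adjusted p = 6.35e-08) and the protease Adamts5 at 9.54 ± 0.38 against 1.42 ± 0.82 (difference 8.13 ± 0.40, adjusted p = 7.47e-08). Fabp4, a fatty acid carrier of capillaries, was higher by 7.64 ± 0.24 (adjusted p = 4.68e-09), and Sox17, an arterial transcription factor gene without reads in the libraries labelled sinusoidal, was at least 183-fold higher than the floor of 3 reads per library. Igll1, the surrogate light chain gene of B cell precursors, fell by 8.53 ± 0.73 in type H (adjusted p = 5.99e-06), and Gp9, a platelet glycoprotein gene, fell by 11.56 ± 1.66 (adjusted p = 0.000284). Limma called 4882 genes, 2383 higher and 2499 lower in type H.

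Of the 14 sinusoidal genes, 14 rose in type H (14 adjusted over the list alone; camera adjusted p = 1.27e-17, adjusted p = 0.00626 with an estimated correlation), with a median of 6.52. Of 16 pan-endothelial genes, 13 rose and 0 fell (13 adjusted over the list alone; camera adjusted p = 1.37e-15, adjusted p = 0.0184 with an estimated correlation), with a median of 6.61. Of 13 genes of venous and inflamed endothelium, 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 2.82e-05, adjusted p = 0.0162 with an estimated correlation). Of 17 tip cell and basement membrane genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 4.93e-10, adjusted p = 0.0126 with an estimated correlation). Of 11 megakaryocyte and platelet genes, 11 fell (11 adjusted over the list alone; camera adjusted p = 3.64e-07, adjusted p = 0.0207 with an estimated correlation). Of 12 B and plasma cell genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 1.87e-08, adjusted p = 0.0207 with an estimated correlation). Of 25 cell cycle genes, 21 fell (23 adjusted over the list alone; camera adjusted p = 1.19e-10, adjusted p = 0.0685 with an estimated correlation), with the nucleotide reductase gene Rrm2 at -3.88 ± 0.38 (adjusted p = 1.76e-05). Of 16 stromal and bone genes, 2 rose and 9 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.00031, adjusted p = 0.107 with an estimated correlation). The lymphatic endothelium list had 1 of 6 genes lower in type H (1 adjusted over the list alone), and did not pass (camera adjusted p = 0.256). The median and the camera direction of the primary cilium list had opposite signs, and that list did not pass.

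The comparison of type H with arterial libraries asks how endomucin-rich vessels differ from arterial cells. Tfpi was higher in type H by 7.64 ± 0.42 (adjusted p = 2.67e-06) and Ackr1 by 7.41 ± 0.61 (adjusted p = 2.36e-05). Icam1 was at 8.66 ± 0.09 in type H and 5.52 ± 0.46 log2 CPM in arterial libraries (difference 3.14 ± 0.31, adjusted p = 5.86e-05), and F8, which encodes clotting factor VIII, was higher by 11.57 ± 1.11 (adjusted p = 5.43e-05). Heyl, a target of Notch, fell by 8.67 ± 1.30 in type H (adjusted p = 0.000759), Cav1 by 2.31 ± 0.29 (adjusted p = 0.000264), and Kitl, the stem cell factor gene, by 2.64 ± 0.45 (adjusted p = 0.00169). Cd200 differed by 0.12 ± 0.16 and did not pass (adjusted p = 0.647), but was lower in type H once the pan-endothelial medians were made equal (-1.73, adjusted p = 0.00137, against 0.901 at the highest over the alternatives). Limma called 3536 genes, 1360 higher and 2176 lower in type H. With the pan-endothelial medians made equal, 10076 genes were called, 286 higher and 9790 lower.

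Of 14 sinusoidal genes, 13 rose in type H against arterial (14 adjusted over the list alone; camera adjusted p = 5.61e-18, adjusted p = 0.00584 with an estimated correlation). Of 13 genes of venous and inflamed endothelium, 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.000474, adjusted p = 0.0379 with an estimated correlation), with Nr2f2, the transcription factor of vein identity, at 5.26 ± 0.70 (adjusted p = 0.00036). Of 16 pan-endothelial genes, 11 rose and 0 fell (13 adjusted over the list alone; camera adjusted p = 2.14e-11, adjusted p = 0.0379 with an estimated correlation), with a median of 2.40. Of 18 immediate early and heat shock genes, 8 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 0.000178, adjusted p = 0.127 with an estimated correlation). Their list no longer passed with the pan-endothelial medians made equal (adjusted p = 0.375). Of 17 arterial genes, 7 fell and 0 rose (8 adjusted over the list alone; camera adjusted p = 0.0041, adjusted p = 0.132 with an estimated correlation). The 17 capillary genes divided into 7 that rose and 6 that fell (7 and 6 adjusted over the list alone), with Plvap, a protein of endothelial diaphragms, at 5.78 ± 0.70 (adjusted p = 0.000197). The list did not pass (camera adjusted p = 0.126). Of 16 stromal and bone genes, 15 fell (16 adjusted over the list alone; camera adjusted p = 2.1e-11, adjusted p = 0.0379 with an estimated correlation). Of 14 neutrophil genes, 13 fell (13 adjusted over the list alone; camera adjusted p = 4.07e-10, adjusted p = 0.118 with an estimated correlation). Of 12 B and plasma cell genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 1.04e-07, adjusted p = 0.0379 with an estimated correlation). Of 8 MHC class II genes, 6 fell (7 adjusted over the list alone; camera adjusted p = 0.000406, adjusted p = 0.113 with an estimated correlation), with the lysosomal protease Ctss at -3.24 ± 0.57 (adjusted p = 0.0021). Of 25 cell cycle genes, 17 fell (21 adjusted over the list alone; camera adjusted p = 1.29e-09, adjusted p = 0.113 with an estimated correlation). The capillary, Notch, immune checkpoint, nitric oxide, primary cilium and interferon response lists had a median, mean or camera direction of opposite sign, and did not pass.

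The comparison of arterial libraries with those labelled sinusoidal asks how arterial cells differ from cells of the sinusoidal label. Gpihbp1 was higher in arterial libraries by 6.76 ± 0.31 (adjusted p = 1.97e-07), the basement membrane collagen Col4a1 by 4.79 ± 0.20 (adjusted p = 1.41e-07), Cxcl12 by 3.92 ± 0.45 (adjusted p = 0.000215), Adipoq by 4.11 ± 0.51 (adjusted p = 0.000383) and the neutrophil granule gene Lcn2 by 2.10 ± 0.29 (adjusted p = 0.000668). Ighm was at 8.73 ± 0.32 in arterial libraries and 10.58 ± 0.20 in those labelled sinusoidal (difference -1.85 ± 0.23, adjusted p = 0.000323), and Pf4 was lower in arterial by a difference of -2.31 ± 0.47 (adjusted p = 0.00778). Hbb-bs, an adult haemoglobin gene whose reads cannot be separated with certainty from those of Hbb-bt, was higher in arterial by 1.95 ± 0.35 (adjusted p = 0.00391). Limma called 1748 genes, 1383 higher and 365 lower in arterial libraries. The count was 977 without arterial replicate 3, 1029 without arterial replicate 2, 1154 without sinusoidal replicate 1 and 1076 without sinusoidal replicate 2, and 2829 with only these 6 libraries fitted (1882 higher and 947 lower). Without arterial replicates 2 and 3, 869 and 829 genes were higher and 160 and 148 lower, and without sinusoidal replicates 1, 2 and 3 the lower genes numbered 97, 99 and 133. Quantile normalization gave 1312 higher and 590 lower genes, rescaling to the same total 1272 and 569, voom 1554 and 739, and limma without the trend 1124 and 217.

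Of 17 capillary genes, 13 rose in arterial libraries over those labelled sinusoidal (14 adjusted over the list alone; camera adjusted p = 3.01e-19, adjusted p = 0.00866 with an estimated correlation). Of 17 arterial genes, 11 rose (12 adjusted over the list alone; camera adjusted p = 1e-13, adjusted p = 0.00866 with an estimated correlation). Of 17 tip cell and basement membrane genes, 14 rose (14 adjusted over the list alone; camera adjusted p = 3.09e-15, adjusted p = 0.00555 with an estimated correlation). Of 18 secreted and membrane niche factors, 10 rose and 1 fell (12 and 3 adjusted over the list alone). Camera gave that list adjusted p = 1.72e-05, or adjusted p = 0.0908 with an estimated correlation, and Kitl was at 4.33 ± 0.45 (adjusted p = 0.000105). Adipoq of the stroma was also higher in arterial libraries, and which cells carry the differences in this list, Kitl and Cxcl12 was not tested. The stromal and bone list also passed (camera adjusted p = 0.00123) and lost the call with an estimated correlation. Its median level was 9.05 log2 CPM in arterial libraries and 6.43 in those labelled sinusoidal. Of 17 genes of immune checkpoint and tolerance, 5 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0029, adjusted p = 0.0492 with an estimated correlation), with the checkpoint gene Vsir at 1.71 ± 0.31 (adjusted p = 0.00405). Of 14 neutrophil genes, 11 rose (13 adjusted over the list alone; camera adjusted p = 8.93e-11, adjusted p = 0.116 with an estimated correlation). Of 11 mural genes, 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00938, adjusted p = 0.103 with an estimated correlation), with the pericyte receptor Pdgfrb at 3.59 ± 0.73 (adjusted p = 0.0082). Of 12 MHC class I genes 0 passed, also over the list alone, and the list had a median of 0.06, a mean of -0.10 and camera adjusted p = 0.973. Of 44 autophagy genes 2 rose (2 adjusted over the list alone), with Lamp1, a lysosomal membrane gene, at 1.80 ± 0.26 (adjusted p = 0.00106). The list did not pass (camera adjusted p = 0.799). Of 6 skeletal muscle genes 0 passed, also over the list alone, with camera adjusted p = 0.605. The MHC class I, primary cilium and lymphatic lists had a median, mean or camera direction of opposite sign, and did not pass.

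**Figure D3:**
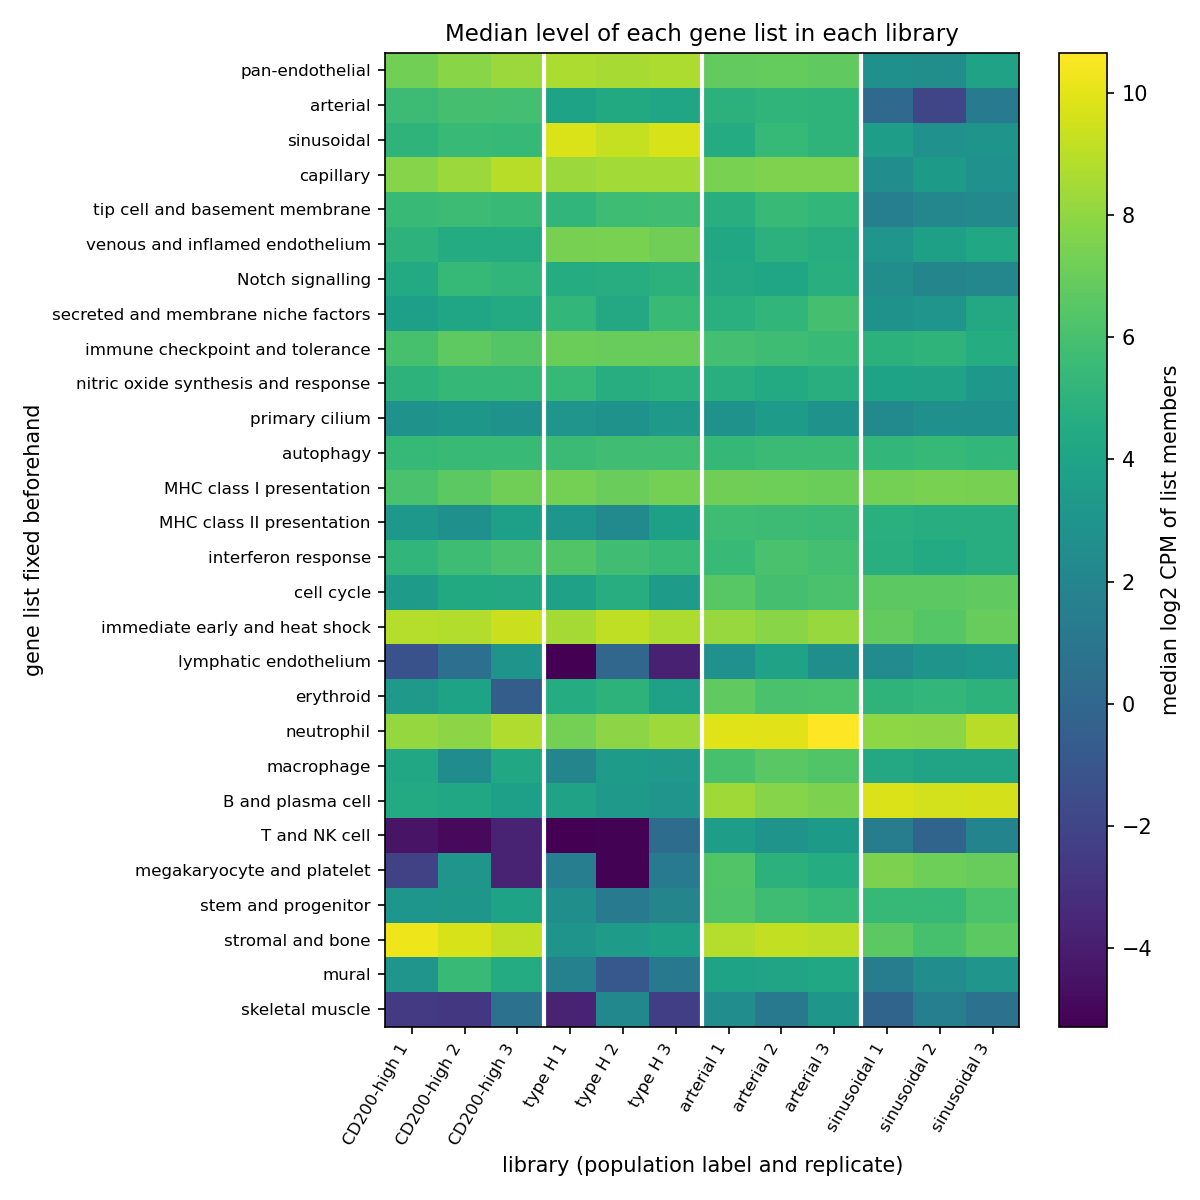
Median log2 CPM of the members of 28 gene lists (vertical) in each of the 12 libraries (horizontal), with colour as the median. The pan-endothelial list had population means of 7.78 in CD200-high, 8.66 in type H, 6.81 in arterial libraries and 3.07 in those labelled sinusoidal.

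Genes higher in 1 population than in each of the other 3 were counted to ask what marks each population. Limma called 269 genes highest in CD200-high, 493 in type H, 171 in arterial libraries and 220 in those labelled sinusoidal. It called 0 in each of 20 simulations without a population effect. Simulated genes varied independently and had to pass against each of the other 3 populations, so 0 was the likely outcome and lends the counts no support. Type H was marked by Fgf23, a phosphate-regulating hormone gene, at 6.63 ± 0.58 log2 CPM (highest library elsewhere -0.21, largest adjusted p = 0.000638), and by Adgrg6, an adhesion receptor gene, at 7.76 ± 0.13 (highest elsewhere 2.24, largest adjusted p = 0.00226). Arterial libraries were marked by Clec3b, which encodes tetranectin, at 5.27 ± 0.19 (highest elsewhere -1.10, largest adjusted p = 0.00131), and by Myoc, the myocilin gene, at 5.80 ± 1.23 (highest elsewhere -1.27, largest adjusted p = 0.00167). CD200-high was marked by BC055402 at 5.39 ± 0.50 (highest elsewhere 1.92, largest adjusted p = 0.00494) and by Gpr135, an orphan receptor gene, at 3.50 ± 0.37 (highest elsewhere -1.06, largest adjusted p = 0.00225). The libraries labelled sinusoidal were marked by Slc5a9, a sugar carrier gene, at 3.31 ± 1.27 (highest elsewhere -1.43, largest adjusted p = 0.00538). A pseudocount of 10 gave 414 genes highest in CD200-high, 277 in arterial libraries and 341 in those labelled sinusoidal. Voom weights gave 506, 773, 314 and 567 genes for CD200-high, type H, arterial and the sinusoidal label. The count for CD200-high was 156 without CD200-high replicate 1, and that for type H 294 and 293 without type H replicates 1 and 3. The count for arterial libraries was 103, 86 and 58 without arterial replicates 1, 2 and 3. The count for the sinusoidal label was 55, 53 and 79 without sinusoidal replicates 1, 2 and 3, and 116 and 99 without arterial replicates 2 and 3.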

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

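Chosen only after the data were seen were the fits with a pseudocount of 1, with limma voom weights, without the 3 libraries labelled sinusoidal, and with each library shifted to the same median of the pan-endothelial list. edgeR and DESeq2, intended for whole reads if these could be recovered, were not run. Limma voom was run on the recovered reads instead. Of 672 values of named genes, 664 were called, and of 168 values of lists, 90. Most of these genes were named because they passed, so the shares of gene values below do not describe all genes tested. Under the pseudocounts of 0.1, 10 and 1, 649, 669 and 672 of the 672 gene values had the same direction and side of the threshold. The numbers were 669 without a filter, 659 of 662 with the stricter one (10 had no value), 651 with quantile normalization, 662 rescaled to the same total and 652 with voom. With only the libraries compared they were 612, without the trend 602, and with a log2 difference of at least 1, 641. In the 3 comparisons without the sinusoidal label, 312 of 339 gene values were the same when its libraries were left out. With the pan-endothelial shift this fell to 279 of 339, with 37 calls lost, 1 gained and 22 reversed. Reversed means a change of sign in a value called before or after, so many reversed values had also lost their call. Leaving out 1 library gave 7461 of 7971, with 508 no longer called, 2 newly called and 0 reversed.

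In the order CD200-high against arterial, type H and the sinusoidal label, type H against the sinusoidal label and arterial, and arterial against the sinusoidal label, an estimated correlation left 0, 2, 8, 7, 6 and 6 lists of 13, 6, 19, 18, 16 and 18. The count of genes highest in 1 population moved most often. A pseudocount of 10 gave 414 in CD200-high (269 as reported), 277 in arterial libraries (171) and 341 in those labelled sinusoidal (220). The count for the sinusoidal label was 342 with quantile normalization, 358 rescaled to the same total and 520 in fits of only 2 populations. Voom gave 506, 773, 314 and 567 in CD200-high, type H (493), arterial and the sinusoidal label. Fits of only 2 populations called 1337 genes between CD200-high and type H (2223) and 2829 between arterial libraries and the sinusoidal label (1748). The cause was not tested.

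Leaving out 1 library gave 1324 to 2457 genes between CD200-high and arterial, and 977 to 1870 between arterial and the sinusoidal label. Genes highest in CD200-high ran from 156 to 280, in type H from 293 to 503, in arterial libraries from 58 to 184 and under the sinusoidal label from 53 to 239. Fewer libraries give fewer degrees of freedom, and the low values came without libraries of the populations counted, or, for the sinusoidal label, of arterial libraries too.

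Scaling moved the direction of the calls. Rescaling to the same total shifted the median difference of all genes from -0.22 to -0.41 between CD200-high and arterial and from -0.22 to -0.53 between CD200-high and the sinusoidal label. It shifted the other 4, in the order above, to -0.18, -0.38, -0.25 and -0.14. Quantile normalization shifted the first to 0.05, type H against arterial from -0.20 to 0.08, and arterial against the sinusoidal label from -0.02 to -0.23. Shifting to the pan-endothelial median moved the first to -1.19, and to 0.83 against type H and -2.05 for type H against arterial, with 3670 genes called between CD200-high and arterial and 10076 between type H and arterial. This alternative assumes that all sorted cells hold equal pan-endothelial RNA. It reversed, between CD200-high and arterial, Sqstm1 (-0.46), Zfp36 (-0.0069) and Junb (-0.16). Between CD200-high and type H it reversed Egfl7 (0.17), Map1lc3b (0.18), B2m (0.27), Tap2 (0.11) and Junb (0.10). Neither these genes nor those named against arterial passed after the shift. Between type H and arterial it reversed Pecam1 (-0.12), Cd200 (-1.73), Egfl7 (-0.15), Col4a1 (-1.14), Entpd1 (-0.20), Klf4 (-0.51), Map1lc3b (-0.87), Tecpr1 (-0.70), Tapbp (-1.19), Irf1 (-0.72), Ifi35 (-0.96), Bst2 (-0.77), Junb (-0.26) and Socs3 (-0.0021), and the autophagy (adjusted p = 0.135) and MHC class I (adjusted p = 0.0125) lists. Of the genes reversed between type H and arterial, Cd200, Col4a1, Map1lc3b, Tecpr1, Tapbp, Irf1, Ifi35 and Bst2 passed after the shift. The other genes reversed there did not. Cd200 and the MHC class I list had not passed before it. The shift moves every gene of a library by the same amount, so small differences turn by construction.

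With the replicate block, libraries of the same number being paired, 2070, 2119, 4751, 4796, 3439 and 1675 genes were called in the 6 comparisons in the order above, and 257, 471, 179 and 194 genes were highest. It ended 17 of 664 gene calls, Tap2 between CD200-high and type H among them (adjusted p = 0.0592). It also ended the nitric oxide list between arterial and the sinusoidal label (adjusted p = 0.0537). It added the niche factor list between CD200-high and arterial (0.0365), the erythroid (0.0473) and neutrophil (0.00206) lists between CD200-high and type H, and the neutrophil list between type H and the sinusoidal label (0.00185). It changed no other call among these 672 gene and 168 list values. Depth set the floor of 3 reads per library for genes without reads. In simulated data at this sample size, 0 of 50 genes changed by 1.5-fold and 6 of 49 changed by 2-fold were called. Nearly all other simulated genes were unchanged, unlike in the data, so these shares do not carry over to the real comparisons.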

Other observations

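The tests of the 3 patterns below were chosen only after their results were seen, and the other splits of the libraries before. Genes of the sinusoidal list took 0.121 ± 0.00858% of the listed reads in CD200-high and 2.05 ± 0.227% in type H (mean ± SD, n = 3 each). They took 0.145 ± 0.0295% in arterial libraries and 0.0365 ± 0.00468%, the lowest share, in those labelled sinusoidal. Mitochondrial genes took 2.71 ± 0.797% in CD200-high, 2.72 ± 0.362% in type H, 5.42 ± 0.963% in arterial libraries and 3.39 ± 0.130% in those labelled sinusoidal. Ribosomal protein genes took 2.44 ± 0.0301%, 2.96 ± 0.154%, 2.75 ± 0.303% and 3.70 ± 0.0782% in the same order. The rank correlation between libraries was 0.855 to 0.865 within CD200-high, 0.879 to 0.926 within type H, 0.908 to 0.919 within arterial and 0.945 to 0.946 within the sinusoidal label. Between populations it was highest for arterial libraries and the sinusoidal label, at 0.802 to 0.871, and 0.683 to 0.726 for type H and the sinusoidal label.

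The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison only 1 of the 10, the real one, gave as many genes. CD200-high and arterial gave 2204 genes and at most 3 in another split, CD200-high and type H 2223 and 20, and CD200-high and the sinusoidal label 4902 and 1. Type H and the sinusoidal label gave 4882 and 1, type H and arterial 3536 and 0, and arterial and the sinusoidal label 1748 and 3. Among splits that part all 3 same-numbered pairs the highest were 3, 20, 0, 0, 0 and 0. For the genes highest in 1 population, 1 of 100 drawn relabelings of the 12 libraries, the real one, gave as many. Relabelings mix libraries of distinct populations, which widens the spread within groups, so few calls come by construction. They therefore cannot decide whether chance gave the 4 counts. The real counts of 269, 493, 171 and 220 for CD200-high, type H, arterial and the sinusoidal label stood against at most 1, 0, 65 and 60.

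The libraries labelled sinusoidal held little endothelial RNA and much RNA of B cell precursors and megakaryocytes, with Vpreb3 at 10.88 ± 0.13 and Pf4 at 10.22 ± 0.08 log2 CPM (mean ± SD, n = 3). An exchange of their labels with type H was argued against, since Emcn and Ly6a differed from type H by -6.94 and -4.87 log2 where they would have to be at least as high. The authors' scaling was argued against too, since the effective size over the listed reads ran only from 0.855 to 1.14 between libraries. With every library rescaled to the same total the pan-endothelial list stayed 5.05 log2 below CD200-high (5.36 as deposited), an outcome that these small factors fixed. RNA of other marrow cells diluting a small share of sinusoidal RNA stays open. The pan-endothelial and sinusoidal lists lay below type H by medians of 6.61 and 6.52, 0.084 apart. The arterial, venous, capillary and tip cell lists lay below it by 2.29, 3.07, 3.43 and 4.92. The CD45- gate should remove such cells and the Sca1+ gate of the label acts against megakaryocytes, but the transcripts leave open whether these gates held. Ptprc was at 6.2 to 6.9 log2 CPM in these libraries, above type H (3.6 to 4.6) and below arterial libraries (7.2 to 7.6). Ly6a was at 3.6 to 4.9, against 8.5 to 10.5 in the other 3 populations. A difference of the sorted cells themselves stays open and was not tested.

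The CD200-high libraries held osteoblast transcripts, with Col1a2 at 14.67 ± 0.32 log2 CPM (mean ± SD, n = 3). Sparc, which is not among the 8 osteoblast genes below, was at 15.01 ± 0.36. It is not particular to bone RNA here, since type H libraries held it at 11.88 to 12.28 with Col1a2 at 4.15 to 5.54. More stroma of every kind was argued against, since the median of 8 osteoblast genes against arterial was 3.23 while that of Lepr, Adipoq and Cxcl12 was -4.76, 7.99 apart. Bone-lining cells or their RNA in the sort may be the source, since the 8 genes differed from the sinusoidal label by about 1 amount (median 3.49, SD 0.498), but against arterial the SD was 1.52, and the CD31+ and Sca1+ gates should remove such cells. Transcription by the CD200-high cells themselves cannot be told apart from this with 3 libraries, all 3 of which ranked by bone share in the reverse order of their pan-endothelial share.

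Ift20 was higher in CD200-high than in the other 3 populations. A rise of the median ciliary gene by the amount of Ift20 was argued against. The medians of the whole list, Ift20 included, ran from -0.09 to 0.37, below the rise of Ift20 in each of the 3 comparisons. The list also passed in none of them. A rise of part of the list stays open. The largest upper quartile of the other ciliary genes over the 3 comparisons was 1.36, slightly above the rise of Ift20 in each. RNA of the bone cells in the same libraries could also carry it, since all 3 CD200-high libraries had the same rank by Ift20 and by bone share, too few libraries to decide. A biological difference between the sorted populations stays open and was not tested.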
